A study of Fragaria vesca with 18 samples.

How the data were processed

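RNA was measured in fruit of the woodland strawberry Fragaria vesca (Hawaii4) at 3 stages of development, with 3 biological replicates per stage, each replicate combining fruit of several plants. Total RNA was extracted with TRIzol, and 2 kinds of library were made at each stage: one from RNA depleted of ribosomal RNA (rRNA-depleted) and one from RNA depleted of polyadenylated RNA (poly(A)-depleted). The 18 libraries were sequenced as stranded pairs of reads on an Illumina HiSeq instrument, per the labels' protocols.

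The authors deposited 1 table of raw counts, with whole numbers per row and library and no normalization, per the file headers and the values. The deposited table holds counts for 61763 rows. Row names carry 5 prefixes, which were read here as 28588 annotated genes (FvH4), 19247 intergenic lncRNAs (LINC), 12662 exonic antisense lncRNAs (exonAS), 821 intronic antisense lncRNAs (intronAS) and 445 intronic sense lncRNAs (INTRONIC). LncRNAs are long RNAs without an annotated protein product. The submitters' processing notes name Trim Galore 0.4.2, STAR 2.5.4b and TopHat2 2.1.2 and give no role for them. The program that counted the reads, its strand setting, the genome build and the annotation release are not given in the sources used here, so reads of a gene and of a row antisense to it cannot be separated with confidence. The authors also deposited the exons of assembled transcripts; the file's source column names Cufflinks. It holds 33162 loci, of which 16 are absent from the count table, and 29 loci occur in the count table under 2 classes. Positions of lncRNAs are printed as that file gives them, counted from 1, on chromosomes that it names Fvb followed by the number. Annotated genes have no position in the deposited files. The place of a row among gene numbers was therefore interpolated from rows and genes with nearly equal counts. Its best correlated nearby gene is the gene numbered near that place with the highest correlation over the 18 libraries. That gene need not overlap the row. In a narrower window 48.3% of exonic antisense rows reached a best correlation over 0.95, and 23.1% did in windows shifted by 3000 gene numbers. No file paired the gene IDs with names: 0 of 28588 IDs matched any of 24946 reference rows, so genes are given by ID only, and the tests of 18 gene lists written beforehand could not be run.

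Library totals ranged from 9.49 to 76.9 M counts. Counts were compared with edgeR 4.0.16 (limma 3.58.1, R 4.3.3): TMM scaling, rows kept by filterByExpr with the group factor, a quasi-likelihood fit with estimated dispersions, and the quasi-likelihood F test. P-values were adjusted by Benjamini-Hochberg over all rows tested, genes and lncRNAs together, and a row was called at an adjusted p under 0.05. Each kind of library had its own fit to 9 libraries with 3 stage groups, which tested 49283 rows in the rRNA-depleted and 48201 in the poly(A)-depleted libraries. A fit to all 18 libraries and 52101 rows gave the difference between library kinds, averaged over the 3 stages, and the interaction of stage and library kind (an F test with 2 degrees of freedom). Normalised CPM (counts scaled to a common library total) use the TMM factors of the same fit. Standard errors of log2 fold changes were derived from the F statistic. Shares of counts were compared by an exact permutation test, two-sided, that exchanged the library kinds within each stage in all 8000 ways.

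The designs, the alternatives and the rule for named rows were fixed before the data were examined, except where stated. The rule takes rows with an adjusted p under 0.05 whose replicates do not overlap between the groups, with a mean of at least 10 CPM (genes) or 2 CPM (lncRNAs) in the higher group, and names the 2 largest rises and 2 largest falls. Because IDs have no names, the rule allows 2 genes and 2 lncRNAs each way. For the interaction, the 2 genes and 2 lncRNAs with the smallest adjusted p and a mean of at least 10 CPM were named. As written beforehand, the rule allowed more rows for the interaction and the comparison of library kinds, and the cut to 2 there was not part of it. Exonic antisense rows filled nearly all lncRNA places, so intergenic lncRNAs named by the same rule were added after seeing the data. The comparison of brown with green stages was also added then, with all its alternatives.

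Other choices tried were DESeq2 1.42.0 on the same rows, median-of-ratios size factors, TMM factors from annotated genes only, library size only, no low-count filter, at least 1 CPM in 3 libraries, an adjusted p under 0.01, an absolute log2 fold change of at least 1, adjustment over lncRNAs alone, a replicate block, a fit of only the 2 stages compared, and leaving out each library in turn. Added after seeing the data were fits with the log2 intergenic share as a covariate, without exonic antisense rows, and without libraries that stood apart. The labels do not say whether equal replicate numbers share fruit or RNA. Equal numbers were taken as pairs where every correlation of deviations from the group means was above 0.1 (rows with a mean of at least 20 counts, log2 of CPM with 0.5 added). Of the comparisons made, this held throughout only for the poly(A)-depleted yellow and brown stages, with 0.43, 0.16 and 0.44, and the blocked fit also called 0 rows there. Between the 2 kinds of library it held at the green and yellow stages (lowest 0.212) but not at brown, where number 2 had -0.182, so the comparison of kinds and the interaction were not taken as paired. In 15 of 18 comparisons between the kinds, a library correlated best with its own number, and at green and yellow every library did. The unpaired fit leaves such shared deviations in the spread.

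The test was tried on simulated data with the real means, library sizes and dispersions, with 100 rows changed 2-fold and 100 changed 4-fold, all with a mean of at least 1 CPM. In the rRNA-depleted yellow against green comparison (49283 rows) it recovered 0% of 2-fold and 15% of 4-fold changes, with 1 false call. In the poly(A)-depleted one (48201 rows) it recovered 0% and 31%, with 5 false calls. For poly(A)-depleted against rRNA-depleted libraries (52101 rows) it recovered 21% and 93%, with 10 false calls. Most 2-fold and 4-fold changes were therefore missed in the simulated yellow against green comparisons, and the other stage comparisons were not simulated. Many more rows were called in the real data than were changed in the simulation. That makes the Benjamini-Hochberg cutoff less strict there, so the recovery in the real comparisons is not known. Intervals and floors given for counts cover counting error only, because reads without molecular identifiers are not independent molecules. Position along ripening, background and neighbours were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.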

Results

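The 18 libraries fall into 6 groups of 3. The stages were immature fruit with green achenes (green), mature fruit with yellow achenes (yellow) and mature fruit with brown achenes (brown); achenes are the small dry fruits on the surface of the strawberry. Poly(A)-depleted libraries held 16.1 ± 0.485 M counts at the green stage, 10.1 ± 1.05 M at yellow and 14.6 ± 5.08 M at brown (mean ± SD, n = 3). The rRNA-depleted libraries held 65.5 ± 10.2, 69.2 ± 5.16 and 61.4 ± 12.8 M. Most assembled lncRNA loci had 1 exon, with 96.5% of intergenic and 97.5% of exonic antisense rows. All libraries were at 0 for 3472 of the 19247 intergenic rows. Unless stated otherwise, n is 3 libraries per group, values are CPM as mean ± SD, and log2 fold changes carry their standard error.

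The first question was how the 2 kinds of library sample lncRNAs. Intergenic lncRNA rows took 6.58 ± 0.806%, 14.0 ± 1.94% and 11.1 ± 5.66% of the counts in poly(A)-depleted green, yellow and brown libraries. In rRNA-depleted libraries they took 1.96 ± 0.105%, 1.98 ± 0.611% and 3.17 ± 1.61%. Exonic antisense rows went the other way, with 20.0 ± 0.129%, 17.2 ± 0.556% and 18.6 ± 1.16% in poly(A)-depleted and 23.3 ± 0.803%, 24.8 ± 1.09% and 22.2 ± 0.504% in rRNA-depleted libraries. One row of this class, exonAS.XLOC_011569, held 752177 to 5435551 counts in rRNA-depleted libraries, with totals of 47.2 to 76.9 M. In poly(A)-depleted libraries it held 2926 to 198032 counts, with totals of 9.49 to 20.4 M. Set against these totals, this row makes most of the class difference averaged over the stages, and more than all of it at green. The class difference therefore says little about the other exonic antisense rows, and the class share without this row was not computed. In rRNA-depleted yellow library 3 its 5435551 counts lay beside 5434940 of FvH4_3g20030. A set of 74 annotated genes whose IDs carry the prefix FvH4_c1g, read here as contig 1, took a mean of 9.38% of poly(A)-depleted and 2.28% of rRNA-depleted counts. All lncRNA rows together took a mean of 29.6% in poly(A)-depleted and 25.9% in rRNA-depleted libraries, a difference of 3.66 percentage points (exact permutation test within stages, two-sided, p = 0.00275, adjusted over the 6 shares compared 0.0033). The differences for intergenic rows, exonic antisense rows and contig 1 genes each had p = 0.00025 (adjusted 0.000375), the smallest that this exact test can give, and these comparisons were added after the data were seen. The share of detected rows (at least 10 counts) that are lncRNAs did not differ by this test, at 47.3% in both kinds of library (difference 0.0257 percentage points, exact p = 0.935, adjusted 0.935).

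**Figure D1:**
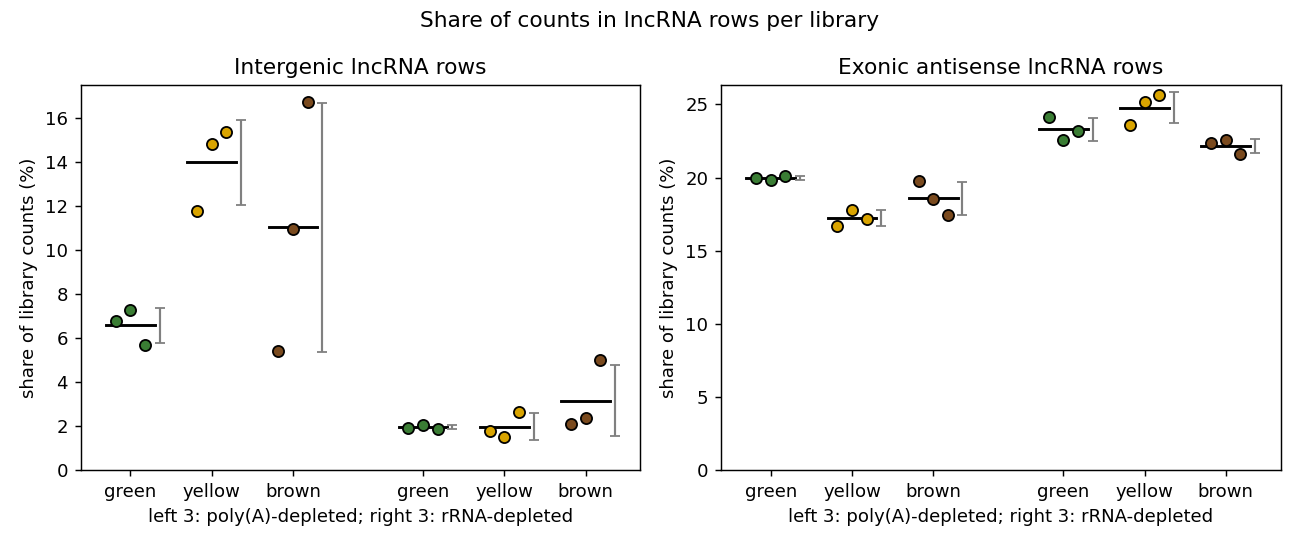
Share of library counts (%) in intergenic (left) and exonic antisense (right) lncRNA rows, by stage, for poly(A)-depleted libraries (left 3 groups) and rRNA-depleted libraries (right 3 groups). Points are libraries, black lines group means and grey bars 1 SD (n = 3); intergenic shares in poly(A)-depleted libraries, with group means of 6.58% to 14.0%, lie above those in rRNA-depleted libraries, with group means of 1.96% to 3.17%.

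Row by row, the intergenic class was mostly higher in poly(A)-depleted libraries. Of 12103 intergenic lncRNAs tested, 9053 were higher and 373 lower in poly(A)-depleted libraries, with a class median log2 fold change of 1.31. Genes with almost no counts in rRNA-depleted libraries (982 genes, at most 20 counts over them) were also higher, at 70.7 ± 10.6, 174.6 ± 32.1 and 264 ± 363 CPM of library totals at the green, yellow and brown stages of poly(A)-depleted libraries, against 14.3 ± 1.25, 13.6 ± 9.72 and 11.7 ± 6.43 CPM. Their choice by low rRNA-depleted counts makes part of this difference. Across the 9 poly(A)-depleted libraries, the intergenic share rose with the level of these genes (Pearson r = 0.722, permutation p = 0.0001, adjusted over the 4 relations computed 0.0004; Spearman rho = 0.95, permutation p = 0.0005; r = 0.876 without the 2 farthest libraries). It also rose with the share of contig 1 genes (r = 0.89, p = 0.0053, adjusted 0.0106; rho = 0.767, p = 0.0226; 0.897 without the 2 farthest). In rRNA-depleted libraries the relation with the almost silent genes was not found (r = 0.414, p = 0.273, adjusted 0.273; rho = 0.25, p = 0.514; 0.0235 without the 2 farthest), and that with contig 1 rested on the 2 farthest libraries (r = 0.721, p = 0.0307, adjusted 0.0409; rho = 0.333, p = 0.377; 0.152 without them). The stages differ in these measures. With stage means removed and an exact test over the 216 exchanges within stages, none of the 4 relations passed: r was 0.853 for the almost silent genes (p = 0.0463, adjusted 0.167; rho = 0.667, p = 0.176; 0.173 without the 2 farthest) and 0.807 for contig 1 (p = 0.236, adjusted 0.236; rho = 0.333, p = 0.556; -0.66 without them) in poly(A)-depleted libraries. In rRNA-depleted libraries it was 0.649 (p = 0.144, adjusted 0.191; rho = 0.5, p = 0.306; 0.527) and 0.852 (p = 0.0833, adjusted 0.167; rho = 0.167, p = 0.889; 0.665). The size of any background part of the intergenic excess is not known. Exonic antisense rows were divided, with 3888 higher and 5788 lower, as were annotated genes, with 9122 higher and 11425 lower. Among the 73 contig 1 genes tested, 43 were higher and 5 lower, with a median log2 fold change of 1.17. FvH4_c1g00210 measured 158 ± 39.4, 810.1 ± 178 and 433 ± 645 CPM at the green, yellow and brown stages of poly(A)-depleted libraries, against 52.0 ± 14.5, 138 ± 120.5 and 29.0 ± 14.0 CPM in rRNA-depleted ones (log2 fold change 2.68 ± 0.56, edgeR adjusted p = 0.000265). Its poly(A)-depleted brown libraries ranged from 59.9 to 1178 CPM, and the log2 fold change was 1.85 without brown library 3. FvH4_c1g00270 was also higher (2.23 ± 0.44, adjusted p = 0.000169). FvH4_6g16770 was lower in poly(A)-depleted libraries, with 41.6 ± 12.9, 14.7 ± 0.727 and 30.6 ± 24.96 CPM against 600.2 ± 17.5, 1615 ± 833 and 1586 ± 785 CPM (-5.44 ± 0.48, adjusted p = 6.92e-08), as was FvH4_1g05480 (-5.27 ± 0.51, adjusted p = 1.45e-07).

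Of the lncRNAs named by the rule, exonAS.XLOC_030429 (chromosome 7, 14270751 to 14272058, plus strand) measured 3.32 ± 1.39, 6.30 ± 0.237 and 2.88 ± 2.103 CPM at the green, yellow and brown stages of poly(A)-depleted libraries, against 0.758 ± 0.343, 0.559 ± 0.519 and 0.0182 ± 0.0163 CPM (edgeR adjusted p = 1.25e-06), with counts 0.811 to 1 of those of its best correlated nearby gene, in libraries with at least 20 counts of both. exonAS.XLOC_023022 (chromosome 5, 27678252 to 27680274, minus strand) was also higher (3.17 ± 0.50, adjusted p = 2.07e-05), with 0.265 to 0.843 of the counts of its best correlated nearby gene. exonAS.XLOC_018476 (chromosome 4, 31390111 to 31392426, minus strand) was lower in poly(A)-depleted libraries (-5.60 ± 0.61, adjusted p = 4.24e-07; -4.67 without rRNA-depleted yellow library 2), with 0.111 to 0.998 of the counts of its best correlated nearby gene. exonAS.XLOC_000181 (chromosome 1, 2894239 to 2895883, plus strand) was lower as well (-5.58 ± 0.53, adjusted p = 1.2e-07), and its counts followed those of FvH4_1g05480 across the 18 libraries, at 0.608 to 0.956 of that gene's counts. In all, 20547 genes and 19661 lncRNAs passed an adjusted p of 0.05 (edgeR, 52101 rows). The size of a typical change depended on scaling, as did the direction of most genes and exonic antisense rows. The median log2 fold change of all rows was 0.40 with TMM over all rows, 0.999 with TMM over annotated genes and 1.88 with library size only. The split of genes into higher and lower was 11949 and 8232 with TMM over annotated genes and 16523 and 3376 with library size only, against 9122 and 11425 with TMM over all rows. That of lncRNAs was 15653 and 4359, and 18911 and 1576, against 13298 and 6363. Exonic antisense rows, mostly lower with TMM over all rows, were mostly higher with these scalings, at 5260 and 4071, and 7449 and 1493.

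The series asks which lncRNAs accompany fruit ripening, which the stage comparisons address. Between green and yellow fruit in rRNA-depleted libraries, FvH4_7g18560 rose from 21.2 ± 17.4 to 10773 ± 13852 CPM (8.99 ± 1.69, edgeR adjusted p = 0.00378), with 90.2, 26424 and 5804.5 CPM in yellow libraries 1, 2 and 3. FvH4_6g41380 rose from 1.01 ± 0.839 to 492 ± 613 CPM (8.93 ± 1.37, adjusted p = 0.000904). FvH4_2g18610 fell from 753 ± 94.0 to 1.63 ± 0.887 CPM (-8.86 ± 0.66, adjusted p = 7.11e-06). FvH4_4g06540 fell from 25.5 ± 4.30 to 0.109 ± 0.0478 CPM (-7.80 ± 0.53, adjusted p = 7.11e-06). Among intergenic lncRNAs, chosen after the data were seen, LINC.XLOC_010907 (chromosome 3, 4545939 to 4547039, minus strand) rose from 0.606 ± 0.439 to 197 ± 189 CPM (8.34 ± 1.11, adjusted p = 0.000312). LINC.XLOC_015303 (chromosome 4, 24545637 to 24548906, plus strand) rose from 0.277 ± 0.337 to 58.6 ± 70.5 CPM (7.76 ± 1.33, adjusted p = 0.002). LINC.XLOC_031650 (chromosome 7, 7115818 to 7117101, minus strand) fell from 3.92 ± 0.610 to 0.167 ± 0.0875 CPM (-4.58 ± 0.62, adjusted p = 0.000368). LINC.XLOC_023251 (chromosome 6, 852391 to 855196, plus strand) fell from 2.55 ± 0.881 to 0.113 ± 0.0942 CPM (-4.42 ± 1.04, adjusted p = 0.0161; 1.96e-05 to 0.0788 over the alternatives). It missed the threshold without green library 2 (0.0550), green library 3 (0.0779) or yellow library 3 (0.0788) and with library size only (0.0630). Without yellow library 2 the log2 fold change was 7.21 for FvH4_7g18560, 7.27 for FvH4_6g41380, 7.45 for LINC.XLOC_010907 and 6.24 for LINC.XLOC_015303. Without green library 1 it was 9.90, 9.85 and 9.11 for the first 3, without green library 3 it was 9.46 for LINC.XLOC_015303, and without yellow library 1 it was -5.17 for LINC.XLOC_023251.

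By the planned rule, exonAS.XLOC_028814 (chromosome 6, 32537950 to 32541699, minus strand) rose from 13.7 ± 9.11 to 6489 ± 7932 CPM (8.88 ± 1.40, edgeR adjusted p = 0.00105). exonAS.XLOC_018468 (chromosome 4, 31267369 to 31268005, minus strand) rose from 58.2 ± 46.8 to 23011 ± 29240.0 CPM (8.63 ± 1.499, adjusted p = 0.00217). exonAS.XLOC_006840 (chromosome 2, 15941343 to 15942176, minus strand) fell from 754 ± 94.4 to 1.65 ± 0.901 CPM (-8.84 ± 0.66, adjusted p = 7.11e-06). exonAS.XLOC_016183 (chromosome 4, 2264323 to 2267571, minus strand) fell from 502 ± 73.3 to 3.47 ± 2.12 CPM (-7.17 ± 0.74, adjusted p = 5.75e-05). The counts of exonAS.XLOC_006840 were 1 to 1.05 times those of FvH4_2g18610 in every library, and those of exonAS.XLOC_018468 were 1 to 1.04 times those of FvH4_4g32700, so these rows measure nearly what the gene rows measure. Those of exonAS.XLOC_016183 were 0.371 to 0.818 of those of its best correlated nearby gene, and those of exonAS.XLOC_028814 12.3 to 36.3 times those of FvH4_6g41380, chosen in the same way. Without yellow library 2 and without green library 1 the log2 fold change was 7.29 and 9.58 for exonAS.XLOC_028814 and 6.86 and 9.52 for exonAS.XLOC_018468, and without yellow library 1 it was -7.79 for exonAS.XLOC_016183. In total 846 genes were higher and 1538 lower in yellow fruit, with 333 and 626 exonic antisense rows and 79 and 45 intergenic lncRNAs. All lncRNAs together gave 418 and 676. With the intergenic share as a covariate 3652 genes and 1778 lncRNAs were called. The counts of genes and lncRNAs fell to 1517 and 648, 1395 and 590, and 1326 and 564 without green libraries 1, 2 and 3. The median log2 fold change of all rows was 0.0042, against -0.19 with library size only.

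**Figure D2:**
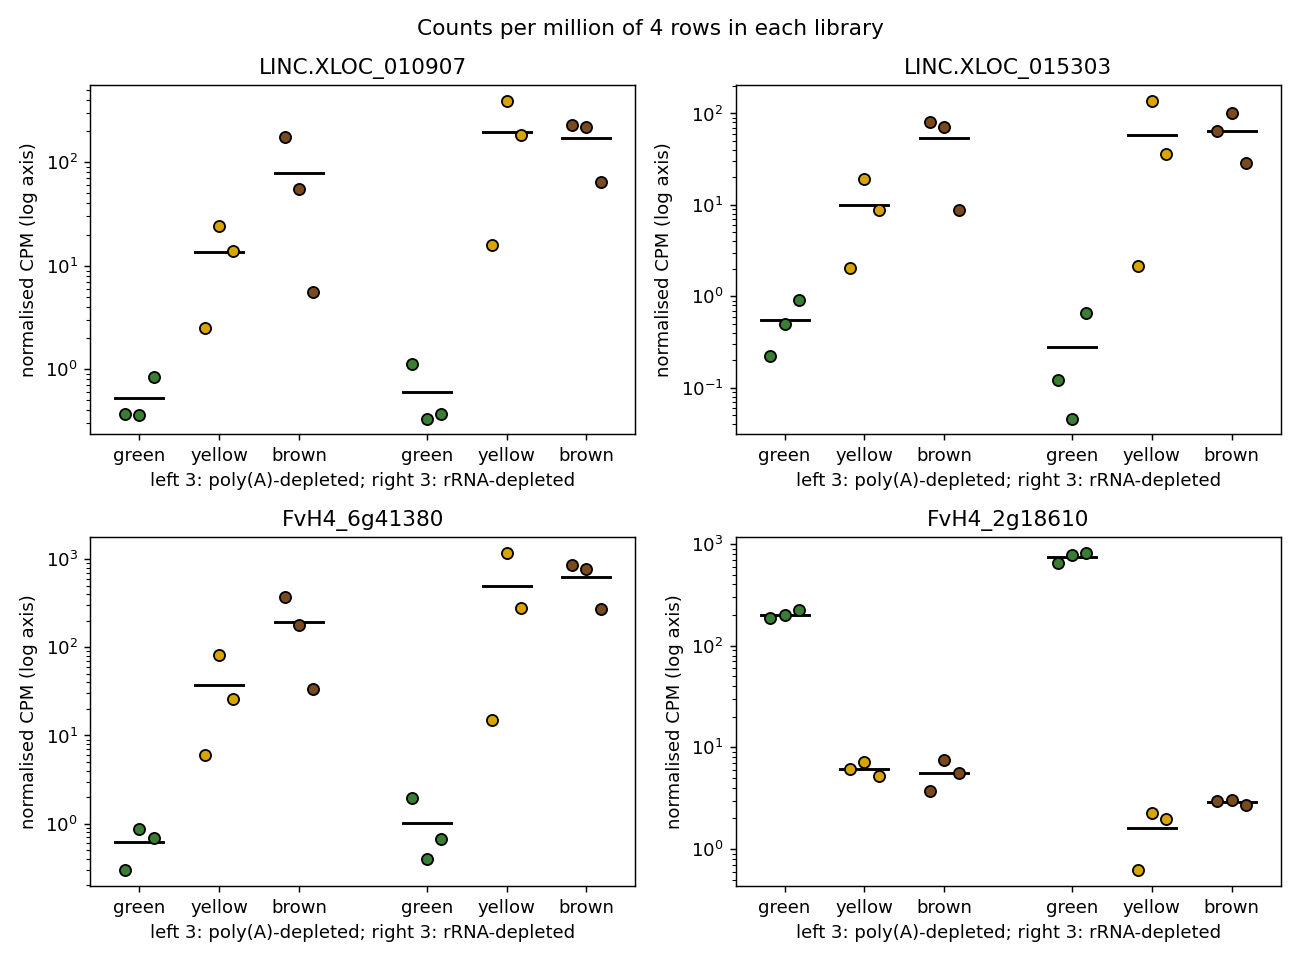
Normalised CPM (log axis) of 2 intergenic lncRNAs and 2 annotated genes in each library, by stage, for poly(A)-depleted libraries (left 3 groups) and rRNA-depleted libraries (right 3 groups); points are libraries and black lines group means (n = 3). In rRNA-depleted libraries LINC.XLOC_010907 goes from a mean of 0.606 CPM at green to 197 CPM at yellow, and FvH4_2g18610 from 753 to 1.63 CPM. Each kind of library is scaled by its own fit, so levels are not on a common scale between the kinds.

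Between yellow and brown fruit in rRNA-depleted libraries no row passed, while the yellow libraries differed from each other. FvH4_7g18560 measured 10773 ± 13852 CPM at yellow and 12620.0 ± 5399 CPM at brown. LINC.XLOC_010907 measured 197 ± 189 and 173 ± 93.2 CPM. For the 241 genes with at least a 4-fold higher level in brown than in green rRNA-depleted fruit (log2 difference of at least 2, at least 50 CPM in one of the stages; chosen after the data were seen), the mean log2 of CPM with 0.5 added was 5.67, 8.16 and 7.16 in yellow libraries 1, 2 and 3 and 8.13, 8.18 and 7.73 in brown libraries 1, 2 and 3. For the 530 genes lower by the same measure it was 5.11, 2.46 and 3.91 in the yellow and 2.66, 2.88 and 3.38 in the brown libraries. edgeR called 0 genes and 0 lncRNAs, with 3809 genes, 1038 intergenic lncRNAs and 1590 exonic antisense rows at an unadjusted p under 0.05. DESeq2 on the same rows called 851 genes (28 higher, 823 lower in brown) and 429 lncRNAs (9 higher, 420 lower). Without yellow library 2, edgeR called 1565 genes and 708 lncRNAs, and the median log2 fold change of all rows was 0.05, against 0.23 with library size only.

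**Figure D3:**
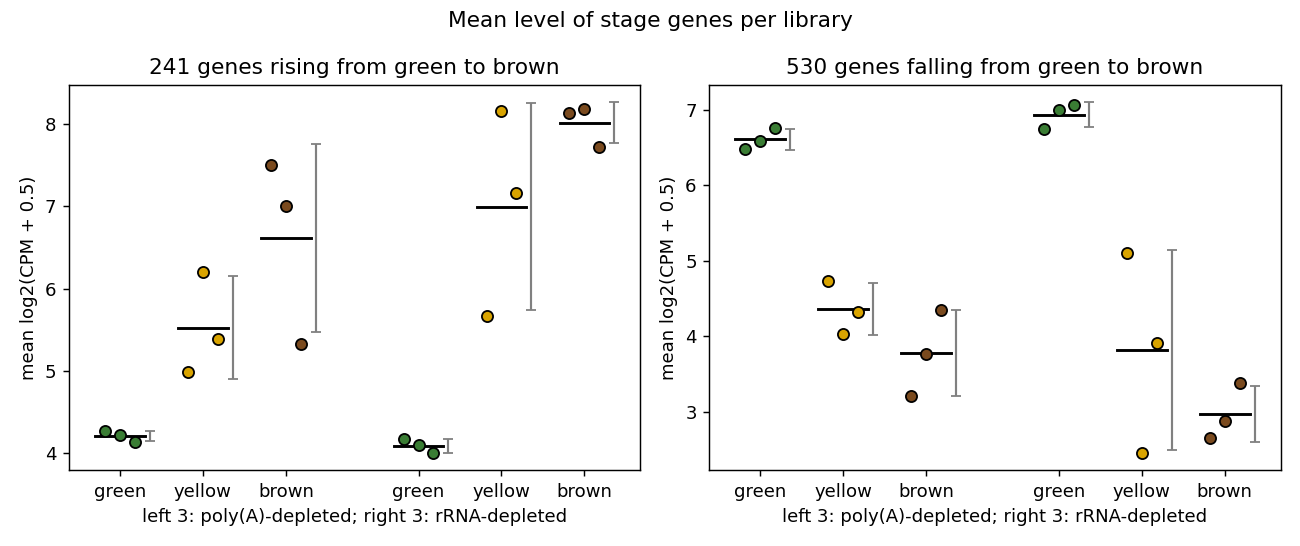
Mean log2 of CPM with 0.5 added over 241 genes rising (left) and 530 falling (right) from green to brown in rRNA-depleted libraries, by stage and library kind; points are libraries, black lines group means and grey bars 1 SD (n = 3). The rRNA-depleted yellow libraries spread from 5.67 to 8.16 on the rising genes, and poly(A)-depleted brown library 3, at 5.33, lies below the other 2 brown libraries at 7.51 and 7.004.

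Between green and brown fruit in rRNA-depleted libraries, a comparison added after the data were seen, FvH4_6g43800 rose from 0.0462 ± 0.0451 to 53.3 ± 41.6 CPM (10.20 ± 2.08, edgeR adjusted p = 0.00398). FvH4_1g22020 rose from 0.0492 ± 0.0195 to 46.8 ± 12.4 CPM (9.81 ± 0.64, adjusted p = 4.28e-06). FvH4_7g25520 fell from 38.8 ± 8.32 to 0.0564 ± 0.0835 CPM (-9.42 ± 0.88, adjusted p = 2.46e-05). FvH4_1g13440 fell from 179.9 ± 46.1 to 0.368 ± 0.250 CPM (-8.94 ± 0.93, adjusted p = 3.94e-05). The intergenic LINC.XLOC_017338 (chromosome 4, 18044640 to 18045669, minus strand) rose from 0.559 ± 0.219 to 184 ± 94.1 CPM (8.36 ± 1.16, adjusted p = 0.000251). LINC.XLOC_009565 (chromosome 3, 23981197 to 23981419, plus strand) rose from 1 count over the 3 green libraries to 578 over the 3 brown ones, a ratio of pooled CPM of 617 (exact 95% interval 110.3 to 24404). LINC.XLOC_012765 (chromosome 3, 29158481 to 29159313, minus strand) fell from 13.9 ± 1.68 to 0.0444 ± 0.0360 CPM (-8.25 ± 0.69, adjusted p = 1.14e-05). LINC.XLOC_023253 (chromosome 6, 861511 to 862497, plus strand) fell from 28.6 ± 5.88 to 0.348 ± 0.188 CPM (-6.36 ± 0.68, adjusted p = 4.37e-05). The log2 fold change of FvH4_6g43800 was 11.18 and 9.54 without green libraries 1 and 2, and that of FvH4_7g25520 was -11.86 and -8.81 without brown libraries 1 and 3. That of LINC.XLOC_009565 was 10.72 and 8.08 without green library 1 and brown library 2, against 8.93 with all, and that of LINC.XLOC_012765 was -8.98 without brown library 1.

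Of the antisense rows in the same comparison, exonAS.XLOC_021188 (chromosome 5, 3803397 to 3804209, minus strand) rose from 3.20 ± 2.65 to 2848 ± 1109 CPM (9.80 ± 2.19, edgeR adjusted p = 0.00708). exonAS.XLOC_028814 rose from 13.7 ± 9.11 to 10340.0 ± 1193 CPM (9.56 ± 1.43, adjusted p = 0.000437). exonAS.XLOC_012515 (chromosome 3, 25870283 to 25871427, minus strand) fell from 98.5 ± 40.6 to 0.189 ± 0.116 CPM (-9.03 ± 1.02, adjusted p = 6.86e-05), with 0.468 to 0.686 of the counts of its best correlated nearby gene. exonAS.XLOC_002052 (chromosome 1, 3807111 to 3808654, minus strand) went from 1470 counts over the green to 2 over the brown libraries, a ratio of pooled CPM of 689 (exact 95% interval 190.3 to 5693), with 0.299 to 0.939 of the counts of its best correlated nearby gene. Its log2 fold change of -9.08 was -11.79 and -8.49 without brown libraries 1 and 2, and without green library 1 the other 2 values were 10.73 for exonAS.XLOC_021188 and 10.25 for exonAS.XLOC_028814. In total 1227 genes were higher and 3336 lower in brown fruit, with 473 and 1515 exonic antisense rows and 420 and 106 intergenic lncRNAs. All lncRNAs together gave 916 and 1647. The counts of genes and lncRNAs fell to 2913 and 1454, 2885 and 1409, and 2702 and 1313 without green libraries 1, 2 and 3. The median log2 fold change of all rows was 0.16, and 0.26 with TMM over annotated genes.

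In poly(A)-depleted libraries, FvH4_4g32700 rose from 10.04 ± 3.84 CPM in green to 2201 ± 2667 CPM in yellow fruit (7.78 ± 1.69, edgeR adjusted p = 0.0260). FvH4_6g41380 rose from 0.616 ± 0.290 to 37.7 ± 38.8 CPM (5.91 ± 1.2003, adjusted p = 0.0207). FvH4_7g02680 fell from 193 ± 81.2 to 0.745 ± 0.627 CPM (-8.04 ± 0.85, adjusted p = 0.00162), and FvH4_6g29300 from 585 counts over the green to 1 over the yellow libraries, a ratio of pooled CPM of 367 (exact 95% interval 65.7 to 14539). The intergenic lncRNAs with the largest rises were again LINC.XLOC_010907, from 0.524 ± 0.276 to 13.7 ± 10.9 CPM (4.69 ± 1.26, adjusted p = 0.0451), and LINC.XLOC_015303, from 0.548 ± 0.351 to 9.93 ± 8.56 CPM (4.17 ± 1.05, adjusted p = 0.0384). LINC.XLOC_026606 (chromosome 6, 4229440 to 4230125, minus strand) fell from 18.4 ± 2.17 to 0.832 ± 0.175 CPM (-4.46 ± 0.77, adjusted p = 0.0115). LINC.XLOC_003965 (chromosome 2, 5817820 to 5818899, plus strand) fell from 5.57 ± 0.807 to 0.324 ± 0.158 CPM (-4.08 ± 1.08, adjusted p = 0.0435). Of these 8, FvH4_6g29300 and FvH4_7g02680 kept an adjusted p under 0.05 in all alternatives run. Without yellow library 2 the other 6 missed it, with 0.108 for FvH4_4g32700, 0.0836 for FvH4_6g41380, 0.157 for LINC.XLOC_010907, 0.149 for LINC.XLOC_015303, 0.0791 for LINC.XLOC_026606 and 0.162 for LINC.XLOC_003965. Without green library 1, 2 or 3 the adjusted p was 0.103, 0.103 and 0.144 for FvH4_4g32700, 0.0864, 0.0711 and 0.102 for FvH4_6g41380, 0.128, 0.118 and 0.142 for LINC.XLOC_010907, 0.117, 0.105 and 0.120 for LINC.XLOC_015303, and 0.111, 0.0962 and 0.140 for LINC.XLOC_003965. Without yellow library 3 it was 0.0741 for FvH4_4g32700, 0.112 for LINC.XLOC_010907, 0.0958 for LINC.XLOC_015303 and 0.152 for LINC.XLOC_003965, which also missed it without yellow library 1 (0.0771), with library size only (0.0740) and with the intergenic share as a covariate (0.0510). Without brown library 2 it was 0.0594 for LINC.XLOC_010907 and 0.0517 for LINC.XLOC_015303. The log2 fold changes without yellow libraries 1 and 2 were 8.44 and 6.06 for FvH4_4g32700, 6.59 and 4.68 for FvH4_6g41380, 5.35 and 3.97 for LINC.XLOC_010907 and 4.82 and 3.29 for LINC.XLOC_015303, and that of FvH4_6g29300 was -10.53 without yellow library 1, against -8.66 with all. Over all alternatives the adjusted p ranged from 5.67e-14 to 0.144 for FvH4_4g32700, 2.14e-07 to 0.102 for FvH4_6g41380, 0.000339 to 0.157 for LINC.XLOC_010907, 0.000368 to 0.149 for LINC.XLOC_015303, 1.38e-07 to 0.0791 for LINC.XLOC_026606 and 4.59e-05 to 0.162 for LINC.XLOC_003965.

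The antisense rows exonAS.XLOC_018468, from 10.1 ± 3.94 to 2248 ± 2712 CPM (7.79 ± 1.69, edgeR adjusted p = 0.0261), and exonAS.XLOC_025857 (chromosome 6, 33840400 to 33841986, plus strand), from 0.271 ± 0.110 to 25.01 ± 34.9 CPM (6.48 ± 1.52, adjusted p = 0.0321), rose in yellow poly(A)-depleted libraries. exonAS.XLOC_016321 (chromosome 4, 3754574 to 3755542, minus strand) fell from 16.8 ± 7.48 to 0.135 ± 0.0549 CPM (-6.89 ± 0.54, adjusted p = 0.000795). exonAS.XLOC_025349 (chromosome 6, 27851370 to 27852308, plus strand) fell from 11.5 ± 6.81 to 0.117 ± 0.146 CPM (-6.61 ± 1.03, adjusted p = 0.00709). The adjusted p of exonAS.XLOC_018468 was 0.103, 0.104 and 0.144 without green libraries 1, 2 and 3 and 0.108 and 0.0745 without yellow libraries 2 and 3 (4.25e-14 to 0.144 over all alternatives). That of exonAS.XLOC_025857 was 0.108, 0.0936, 0.132, 0.121 and 0.0575 in the same fits (4.18e-06 to 0.132). That of exonAS.XLOC_025349 was 0.0570 without yellow library 2 (4.52e-08 to 0.0570). The log2 fold changes without yellow libraries 1 and 2 were 8.46 and 6.10 for exonAS.XLOC_018468 and 7.18 and 4.13 for exonAS.XLOC_025857, and -7.81 without yellow library 1 for exonAS.XLOC_025349. In libraries with at least 20 counts of both, the counts of exonAS.XLOC_016321 were 3.91 to 8.296 times and those of exonAS.XLOC_025349 0.205 to 0.382 of those of the best correlated nearby gene. Those of exonAS.XLOC_025857 were 3.37 to 34.6 times those of FvH4_6g43800, chosen in the same way. The correlations of the last 2 pairs were 0.891 and 0.906, and these genes may not be the ones the rows overlap. Over all rows, 430 genes were higher and 2510 lower in yellow fruit, with 191 and 1202 exonic antisense rows and 781 and 50 intergenic lncRNAs. All lncRNAs gave 994 higher and 1273 lower. Genes and lncRNAs called were 7353 and 6603 with DESeq2, 13816 and 12546 in a fit of only the 2 stages compared, 1361 and 812 with library size only, and 1376 and 576 with the intergenic share as a covariate. The genes almost silent in rRNA-depleted libraries also rose in poly(A)-depleted libraries, from 70.7 ± 10.6 to 174.6 ± 32.1 CPM of library totals, and with the intergenic share as a covariate 39 intergenic lncRNAs were higher and 15 lower. That share rises with the stage and is made of the same rows, so background and changed intergenic RNA are not separated. With TMM over annotated genes, 2398 lncRNAs were higher and 1381 lower, with 1151 and 2521 genes and 548 and 1321 exonic antisense rows. The median log2 fold change of all rows was 0.19, 0.43 and 0.77 with TMM over all rows, TMM over annotated genes and library size only. The counts of genes and lncRNAs were 808 and 365, 908 and 407, and 621 and 281 without green libraries 1, 2 and 3. They were 1754 and 1181, 324 and 147, and 422 and 219 without yellow libraries 1, 2 and 3. They were 9426 and 9214 without brown library 1 and 10888 and 9411 without brown library 3. The brown libraries are in neither group and enter through the scaling, the filter and the estimate of the spread.

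Between yellow and brown fruit in poly(A)-depleted libraries, brown library 3 lay apart from the other brown libraries. LINC.XLOC_010907 measured 13.7 ± 10.9 CPM at yellow and 79.0 ± 87.6 CPM at brown, and FvH4_4g32700 2201 ± 2667 and 6481 ± 5294 CPM. On the 241 genes rising from green to brown, brown libraries 1 and 2 had a mean log2 of 7.51 and 7.004 and brown library 3 one of 5.33, against 4.98, 6.21 and 5.38 in yellow libraries 1, 2 and 3. edgeR called 0 genes and 0 lncRNAs, with 2698 genes, 247 intergenic lncRNAs and 1460 exonic antisense rows at an unadjusted p under 0.05. DESeq2 called 33 genes and 19 lncRNAs, all higher in brown fruit. Without brown library 3, edgeR called 9187 genes and 7079 lncRNAs, and the median log2 fold change of all rows was 0.0070, against -0.26 with library size only.

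Between green and brown fruit in poly(A)-depleted libraries, also added after the data were seen, FvH4_5g06470 rose from 3.15 ± 0.882 to 6119 ± 6611 CPM (10.92 ± 2.60, edgeR adjusted p = 0.0402; 3.66e-12 to 0.203 over the alternatives). FvH4_6g19300 rose from 4.06 ± 0.668 to 6052 ± 5388 CPM (10.54 ± 2.46, adjusted p = 0.0373; 1.79e-12 to 0.205). FvH4_2g39620 fell from 1211 ± 597 to 4.16 ± 4.05 CPM (-8.17 ± 1.14, adjusted p = 0.00367). FvH4_4g34900 fell from 132 ± 54.2 to 0.455 ± 0.0966 CPM (-8.14 ± 1.07, adjusted p = 0.00295). LINC.XLOC_010907 rose to 79.0 ± 87.6 CPM (7.22 ± 1.37, adjusted p = 0.0152; 2.12e-09 to 0.0812). LINC.XLOC_015303 rose to 53.8 ± 39.2 CPM (6.60 ± 1.11, adjusted p = 0.00883; 4.9e-10 to 0.0531). LINC.XLOC_023253 fell from 14.7 ± 4.32 to 0.330 ± 0.204 CPM (-5.35 ± 0.99, adjusted p = 0.0139; 5.73e-06 to 0.0837). LINC.XLOC_000835 (chromosome 1, 11531436 to 11531987, plus strand) fell from 7.97 ± 2.49 to 0.409 ± 0.171 CPM (-4.28 ± 0.64, adjusted p = 0.00527). Without green libraries 1, 2 and 3 and brown library 2 the adjusted p was 0.156, 0.159, 0.203 and 0.1 for FvH4_5g06470 and 0.150, 0.150, 0.205 and 0.0958 for FvH4_6g19300. It was 0.0812, 0.0811 and 0.0810 for LINC.XLOC_010907 without green libraries 1, 2 and 3. It was 0.0531 and 0.0527 for LINC.XLOC_015303 without green libraries 1 and 2, and 0.0672, 0.0837 and 0.0639 for LINC.XLOC_023253 without green libraries 1 and 3 and brown library 2. Without brown library 1 the log2 fold change was 9.79 for FvH4_5g06470, 9.79 for FvH4_6g19300 and 5.99 for LINC.XLOC_010907, and without brown library 3 it was -9.32 for FvH4_2g39620 and -5.99 for LINC.XLOC_023253.

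Of the antisense rows, exonAS.XLOC_021188 rose from 1.59 ± 0.426 to 2820.0 ± 3080.3 CPM (10.79 ± 2.52, edgeR adjusted p = 0.0373; 1.91e-11 to 0.183 over the alternatives), and its counts were 0.315 to 0.50 of those of FvH4_5g06470 in libraries with at least 20 counts of both. exonAS.XLOC_018468 rose to 6616 ± 5396 CPM (9.35 ± 1.80, adjusted p = 0.0166; 1.21e-20 to 0.149). exonAS.XLOC_005632 (chromosome 2, 28411367 to 28412428, plus strand) fell from 1073 ± 519.6 to 3.51 ± 3.37 CPM (-8.24 ± 1.10, adjusted p = 0.00315), with counts 0.780 to 1 of those of FvH4_2g39620. exonAS.XLOC_006266 (chromosome 2, 8496318 to 8496726, minus strand) had 340 counts over the green and 0 over the brown libraries, at least 102.7-fold lower with a floor of 3 counts over the group (adjusted p = 0.0180; 4.25e-06 to 0.0987), with 0.885 to 1 of the counts of its best correlated nearby gene in libraries with at least 20 of both. Without green libraries 1, 2 and 3 and brown library 2 the adjusted p was 0.144, 0.146, 0.183 and 0.0895 for exonAS.XLOC_021188 and 0.0995, 0.114, 0.149 and 0.0601 for exonAS.XLOC_018468. It was 0.0666, 0.0987 and 0.0501 for exonAS.XLOC_006266 without green libraries 2 and 3 and brown library 2. The log2 fold change was 9.63 for exonAS.XLOC_021188 and 8.69 for exonAS.XLOC_018468 without brown library 1, and -9.37 for exonAS.XLOC_005632 without brown library 3. In total 297 genes were higher and 1443 lower in brown fruit, with 104 and 630 exonic antisense rows and 202 and 26 intergenic lncRNAs. All lncRNAs gave 320 and 666, and 113 and 419 with library size only. Genes and lncRNAs called were 4049 and 3711 with DESeq2, 1120 and 560 in a fit of only the 2 stages compared, and 3935 and 2289 with the intergenic share as a covariate. The counts of genes and lncRNAs were 872 and 418, 864 and 404, and 733 and 335 without green libraries 1, 2 and 3. They were 6312 and 6345, 705 and 358, and 5747 and 4280 without brown libraries 1, 2 and 3. The lncRNA count was 654 and 608 without yellow libraries 2 and 3. The median log2 fold change of all rows was 0.15, 0.27 and 0.45 with TMM over all rows, TMM over annotated genes and library size only.

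**Figure D4:**
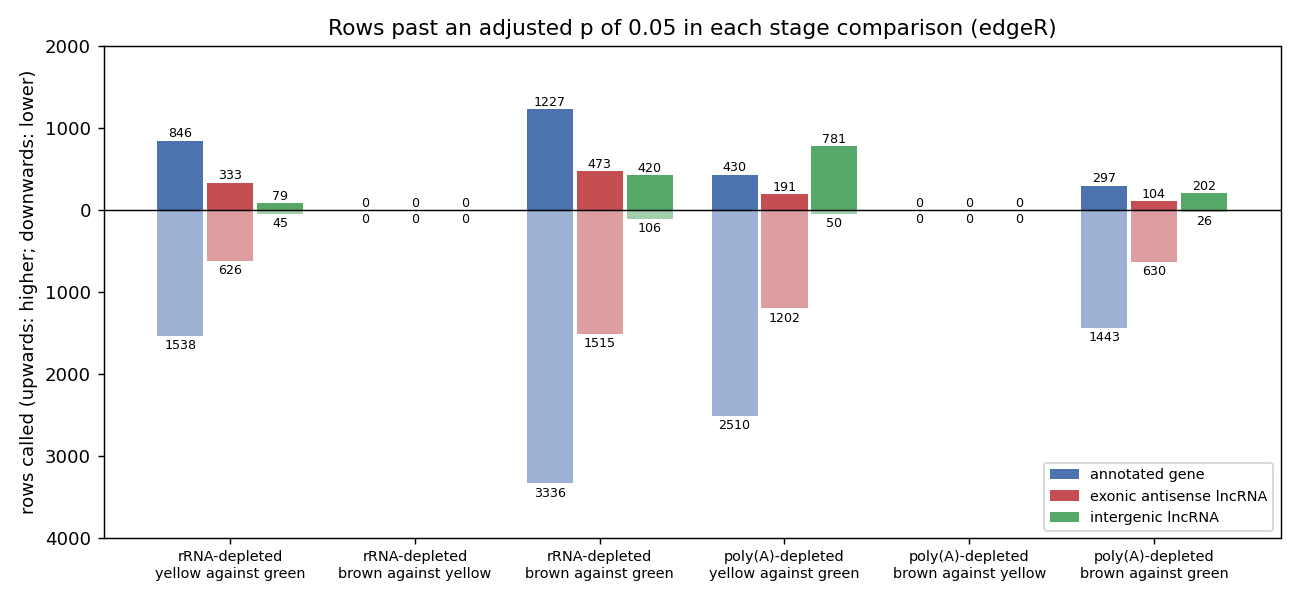
Number of annotated genes, exonic antisense rows and intergenic lncRNAs with an edgeR adjusted p under 0.05 in each stage comparison; bars upwards are rows higher in the later stage and bars downwards rows lower. Genes called lower outnumber those called higher in each of the 4 comparisons with green fruit (1538 against 846 and 3336 against 1227 in rRNA-depleted, 2510 against 430 and 1443 against 297 in poly(A)-depleted libraries), and brown against yellow has 0 calls.

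Whether the stages differ in the same way in both kinds of library was tested by the interaction of stage and library kind. FvH4_7g29870 measured 0.492 ± 0.250, 41.8 ± 13.3 and 13.8 ± 3.54 CPM at green, yellow and brown in rRNA-depleted libraries, against 1.72 ± 0.964, 4.05 ± 0.540 and 2.87 ± 1.28 CPM in poly(A)-depleted ones (edgeR adjusted p = 0.0056). FvH4_2g16730 measured 2.09 ± 0.698, 64.5 ± 5.27 and 21.7 ± 7.59 against 4.34 ± 0.725, 9.504 ± 2.91 and 6.21 ± 1.35 CPM (adjusted p = 0.00741). LINC.XLOC_008482 (chromosome 3, 9765279 to 9769644, plus strand) measured 2.72 ± 0.589, 47.2 ± 18.7 and 16.0 ± 7.51 against 7.82 ± 0.729, 13.1 ± 2.16 and 10.6 ± 2.79 CPM (adjusted p = 0.0327). exonAS.XLOC_008372 (chromosome 3, 8207789 to 8209953, plus strand) measured 3.02 ± 1.59, 295 ± 241 and 127 ± 68.3 against 5.59 ± 0.933, 12.4 ± 1.91 and 12.5 ± 4.55 CPM (adjusted p = 0.0337), with 1.05 to 2.09 times the counts of its best correlated nearby gene.

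The adjusted p of FvH4_7g29870 ranged from 3.66e-08 to 0.242 over the alternatives and was above 0.05 in 1, library size only. That of FvH4_2g16730 ranged from 1.83e-08 to 0.252 and was also above it with library size only, without rRNA-depleted green libraries 2 and 3 (0.0519 and 0.0651) and without poly(A)-depleted green libraries 1 and 2 (0.0643 and 0.0518), and was 0.05 without rRNA-depleted green library 1. LINC.XLOC_008482 (3.52e-05 to 0.485) and exonAS.XLOC_008372 (1.4e-05 to 0.168) each missed the threshold in 11 alternatives. Without rRNA-depleted green libraries 1, 2 and 3 their adjusted p was 0.106, 0.116 and 0.134, and 0.106, 0.168 and 0.158. Without poly(A)-depleted green libraries 1, 2 and 3 it was 0.125, 0.105 and 0.0613, and 0.125, 0.105 and 0.0727. Without poly(A)-depleted yellow libraries 1, 2 and 3 it was 0.0609, 0.0857 and 0.0994, and 0.0594, 0.0875 and 0.0994. It was also 0.0506 for exonAS.XLOC_008372 without rRNA-depleted brown library 1, 0.485 and 0.135 with library size only, and 0.074 for LINC.XLOC_008482 with TMM over annotated genes. In total 32 genes and 12 lncRNAs passed, of which 4 lncRNAs were intergenic and 8 exonic antisense. DESeq2 gave 1083 and 598, the replicate block 5993 and 3093, and library size only 1 and 0. The counts of genes and lncRNAs were 1 and 0, 1 and 0, and 5 and 1 without poly(A)-depleted green libraries 1, 2 and 3. They were 9 and 3, 4 and 2, and 4 and 1 without yellow libraries 1, 2 and 3, and 727 and 612, and 3820 and 2206 without brown libraries 1 and 3. Without rRNA-depleted green libraries 1, 2 and 3 the counts were 2 and 1, 2 and 1, and 3 and 1. They were 105 and 59 without yellow library 1, 152 and 74 without yellow library 2 and 180 and 85 without brown library 3. The gene count was 19 without brown library 1.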

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

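The tests in this part were chosen after the results they concern were seen, except the planned interaction test and the test of even background as the whole cause of the position of poly(A)-depleted brown library 3, whose prediction was written first.

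The interaction test found stage differences that differ between the library kinds for 32 genes and 12 lncRNAs. Among them were FvH4_7g29870 (edgeR adjusted p = 0.0056), FvH4_2g16730 (0.00741), LINC.XLOC_008482 (0.0327) and exonAS.XLOC_008372 (0.0337), each with a larger rise from green to yellow in rRNA-depleted libraries. Of 30 drawn splits of the libraries, 1, the real one, gave as many genes and 1 gave as many lncRNAs, and the highest of the others was 0, but the other splits mix the kinds and put the difference between them into the spread, so they do not test chance. The 4 named rows lost their calls in 1, 6, 11 and 11 of 27, 27, 27 and 26 alternatives. The counts are not settled either: they ranged from 1 to 3820 genes and from 0 to 2206 lncRNAs when single libraries were left out. With the replicate block they were 5993 and 3093. Numbers were not taken as pairs because 1 of the 9 correlations between kinds, at brown, was below 0.1. Green and yellow libraries did behave as pairs, so the unpaired counts of 32 and 12 leave out a pairing that these stages show.

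Of 11592 exonic antisense rows with at least 500 counts, 887 (7.65%) differed from a gene by a mean absolute log2 ratio under 0.1 over the libraries, and they held 32.1% of the counts of their class. To test for the same reads counted in both rows, 1429 pairs of all classes were chosen in the rRNA-depleted libraries alone, and in the poly(A)-depleted libraries the variance about each pair's own ratio was a median of 1.22 times that of independent counts (2.63 times without allowing for that ratio), with 48.4% of pairs under 1. This does not separate the same reads counted in both rows from a separately sequenced antisense RNA that follows its gene, because reads found in only one of the rows also raise the variance. Reads shared with a similar gene elsewhere in the genome are argued against by 881 of the 890 pairs found over all libraries lying on the same chromosome. Over these 890 pairs the variance, not allowing for a pair's own ratio, was a median of 0.123 times that of independent counts. It was under 1 in 89.8% of them, but they were chosen for closeness in the same libraries. exonAS.XLOC_006840 and FvH4_2g18610 had equal counts in rRNA-depleted brown libraries 1, 2 and 3 (175, 181 and 182). In green library 2 they had 68617 and 68550. This argues against separately sequenced reads for this pair. The strand of the reads counted is not known, so whether such rows, exonAS.XLOC_006840 and exonAS.XLOC_018468 among them, hold antisense RNA stays open.

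Poly(A)-depleted brown library 3 lay apart from brown libraries 1 and 2, with correlations of 0.636 and 0.741 against 0.862 to 0.927 with the yellow libraries. For 982 genes nearly silent in rRNA-depleted libraries it held 682.5 CPM (8284 counts; 95% Wilson interval 668 to 697, counting error only), 3.23 times the highest other library, which is consistent with background reads as part of the cause. As the whole cause, even background should lower rising and stable genes of like level alike, but the median log2 ratio of 236 rising genes differed from that of 673 matched stable genes by -0.649 (95% interval -0.782 to -0.523); this fell between the bounds written beforehand for either answer, and gene lengths were not used, so the question stays open. Between the green mean (0) and the brown mean (1), which includes brown library 3, the position of that library on the rising genes was 0.465. Brown libraries 1 and 2 lay at 1.37 and 1.16. On the falling genes it lay at 0.799, against 1.199 and 1.002. These positions also fit fruit that was less ripe, or a wrong label. The rRNA-depleted library of the same stage and number lay at 0.927 on the rising and 0.897 on the falling genes, but whether it shares fruit is not known. Background and ripeness may both contribute, and the data do not separate them.

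No row was called between yellow and brown fruit by edgeR in either kind of library, with 3809 genes in rRNA-depleted and 2698 in poly(A)-depleted libraries at an unadjusted p under 0.05, and DESeq2 called 851 and 33 genes. In the rRNA-depleted set, leaving out yellow library 2 gave 1565 genes with fewer reads. That library stood apart, so leaving it out also lowers the spread, and of 9 single libraries left out only 1 moved the count. The remaining reads thus sufficed for calls at a lower spread, but read number was not tested by itself. Yellow libraries of unlike ripeness in the rRNA-depleted set fit, since their range on the rising genes was 5.47 times the larger range of the green and brown libraries, and 3.64 times on the falling genes, which makes it a candidate explanation there, found and tested on the same data. In the poly(A)-depleted set the yellow range was 0.508 and the brown one 0.907, and leaving out brown library 3 with all yellow libraries kept gave 9187 genes, which argues against unlike ripeness of the yellow libraries as the whole cause there. A swap of rRNA-depleted yellow library 2 with brown library 3 cannot be told apart from this, because brown library 3 was nearer to brown than to yellow libraries 1 and 3 by a ratio of gaps of 1.4 to the nearest library and 3.05 to their means on the rising genes, and 1.04 and 1.83 on the falling genes, against a bound of 3.

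The stage comparisons rest on 6 libraries, which make 10 splits, too few for a share under 0.05. For yellow against green, 1 of 10 splits, the real one, gave as many calls, with 2384 genes and 1094 lncRNAs in rRNA-depleted and 2940 genes and 2267 lncRNAs in poly(A)-depleted libraries and 0 in the highest other split. For brown against green it was also 1 of 10, with 4563 genes and 2563 lncRNAs against 0 in rRNA-depleted, and 1740 genes and 986 lncRNAs against 82 and 97 in poly(A)-depleted libraries. For brown against yellow all 10 of 10 gave as many as the real split, which had 0. The highest other split had 2217 genes and 1067 lncRNAs in rRNA-depleted libraries, with yellow library 2 beside brown libraries 1 and 2, and 2098 genes and 1394 lncRNAs in poly(A)-depleted libraries, with brown library 3 beside yellow libraries 2 and 3. These splits point to a structure of the samples other than the labelled stages. In the poly(A)-depleted set, equal numbers of these stages were taken as pairs from their correlations, which the labels do not state. If they are pairs, the 4 splits that part every pair, the real one included, all had 0 calls, and the others keep some pairs together. For poly(A)-depleted against rRNA-depleted libraries, 1 of 30 drawn splits, the real one, had as many calls (20547 genes and 19661 lncRNAs, highest other 9815 and 10934). This share of 0.0333 is the smallest that 30 splits can give, so chance is argued against at 0.05 and no further, and the splits do not keep equal numbers together.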

How the results depend on the processing

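The fits with the intergenic share as a covariate, without exonic antisense rows, and without libraries that stood apart, and the whole brown against green comparison with its alternatives, were chosen after the results were seen. Pairs of counts are annotated genes and lncRNAs, and where no reason is given the cause was not tested.

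For poly(A)-depleted against rRNA-depleted libraries, both counts stayed within 1.5 times in all alternatives except 9739 lncRNAs without exonic antisense rows, where fewer rows were tested; leaving out single libraries gave 19641 to 21124 genes and 18760 to 20152 lncRNAs. The lncRNA share difference of 3.66 points was 2.86 to 4.43 with single libraries left out, 6.61 without the 10 rows with the most counts and unchanged in the replicate block (exact sign-flip p = 0.00391, the smallest possible). It was 0.0257 for detected rows (exact p = 0.935), and it reversed to -4.82 for exonic antisense rows alone, mostly through exonAS.XLOC_011569.

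At an adjusted p under 0.01, the counts were 1275 and 523 for rRNA-depleted yellow against green, 2487 and 1185 for brown against green, 504 and 217 for poly(A)-depleted yellow against green, 640 and 295 for brown against green, and 3 and 1 for the interaction, by construction of a stricter threshold. An absolute log2 fold change of at least 1 left 1470 lncRNAs in poly(A)-depleted yellow against green. Adjustment over lncRNAs alone left 3 in the interaction.

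With DESeq2 the counts were 851 and 429 for rRNA-depleted brown against yellow, 7353 and 6603 for poly(A)-depleted yellow against green, 33 and 19 for brown against yellow, 4049 and 3711 for brown against green, and 1083 and 598 for the interaction. With library size only they were 1361 and 812 for poly(A)-depleted yellow against green, 532 lncRNAs for brown against green, and 1 and 0 for the interaction. TMM over annotated genes gave 3779 lncRNAs in poly(A)-depleted yellow against green and 21 and 6 in the interaction, and median-of-ratios size factors gave 19 lncRNAs there. Without a low-count filter rRNA-depleted brown against yellow had 85 and 36. A fit of only the 2 stages compared gave 13816 and 12546 for poly(A)-depleted yellow against green, which leaves out the spread of the brown libraries, and 1120 and 560 for brown against green. The replicate block gave 5993 and 3093 in the interaction; the labels do not say that equal numbers share fruit, although 8 of 9 correlations of deviations between library kinds within a stage were above 0.1 (lowest -0.18), against 7 of 18 between stages.

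With the intergenic share as a covariate the counts were 3652 and 1778 for rRNA-depleted yellow against green, 1376 and 576 for poly(A)-depleted yellow against green, and 3935 and 2289 for brown against green. Without exonic antisense rows, which tests fewer rows, lncRNAs numbered 140, 504, 612, 195 and 5 in rRNA-depleted yellow and brown against green, poly(A)-depleted yellow and brown against green, and the interaction. Without yellow library 2 and brown library 3 of the same kind, yellow against green, brown against yellow and brown against green had 3597 and 1655, 3489 and 1665, and 8246 and 4535 in rRNA-depleted, and 6798 and 5177, 6942 and 5575, and 5318 and 3784 in poly(A)-depleted libraries. Without brown library 3 of both kinds the interaction had 4939 and 2818. Removing libraries chosen because they stood apart can raise counts by its own construction, so these are not estimates of the number of changed genes. Not every such removal raised them: without poly(A)-depleted yellow library 2 alone, yellow against green of that kind fell to 324 and 147.

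Leaving out single libraries gave, in rRNA-depleted libraries, 1326 to 3089 genes and 564 to 1427 lncRNAs for yellow against green, 0 to 1565 and 0 to 708 for brown against yellow (highest without yellow library 2), and 2702 to 6377 and 1313 to 3844 for brown against green. In poly(A)-depleted libraries it gave 324 to 10888 and 147 to 9411 for yellow against green (lowest without yellow library 2, highest without brown library 3), 0 to 9187 and 0 to 7079 for brown against yellow (highest without brown library 3), and 705 to 6312 and 335 to 6345 for brown against green. For the interaction it gave 1 to 3820 and 0 to 2206 (highest without poly(A)-depleted brown library 3).

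Of the alternatives for named rows with a fold change, 1080 kept the call, 76 lost it and 0 reversed direction. The 76 lay in yellow against green of rRNA-depleted (4) and poly(A)-depleted libraries (42) and in poly(A)-depleted brown against green (30). With the replicate block the adjusted p was 0.0534 for LINC.XLOC_010907 in poly(A)-depleted yellow against green, and 0.0761 for FvH4_5g06470, 0.0564 for FvH4_6g19300 and 0.0699 for exonAS.XLOC_021188 in brown against green. The other settings written beforehand for gene lists were not run, because no gene ID matched a name. In the simulated yellow against green comparisons 2-fold changes were recovered in 0% of cases; the other stage comparisons were not simulated.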

Other observations

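The tests in this part were all chosen after the stage comparisons had been seen; the predictions for neighbouring intergenic loci and neighbouring genes were written before their own results.

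The stage changes were compared between the 2 kinds of library, which share no library. The labels do not say whether they share fruit, and deviations of equally numbered libraries correlated in 8 of 9 pairs between the kinds (-0.182 to 0.591). The counts given as by chance treat the kinds as independent and so do not allow for shared material. Of 1528 genes lower in yellow than green rRNA-depleted fruit and tested in both kinds, 869 were also called lower in poly(A)-depleted fruit, against 155 by chance, and 95.9% had the same sign (55.2% of all genes called or not had the same sign). Of 838 genes called higher, 44 were also called higher (14.5 by chance), 69.0% had the same sign and 1 was called in the opposite direction. For brown against green the shared calls were 1350 of 3293 genes lower (192 by chance) and 156 of 1220 higher (14.6 by chance), with 97.4% of the 3293 and 99.0% of the 1220 of the same sign, against 78.4% of all genes called or not. For intergenic lncRNAs, 17 of 39 lower (0.204 by chance) and 5 of 60 higher (4.88 by chance) were shared in yellow against green, with 38 of the 39 and 57 of the 60 of the same sign, against 64.8% of all intergenic rows called or not. The shared calls were 21 of 98 lower (0.266 by chance) and 50 of 394 higher (8.23 by chance) in brown against green, with 91.8% and 99.7% of the same sign against 81.9%.

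Neighbouring intergenic loci under 2000 nt apart changed together between green and yellow rRNA-depleted fruit, with a correlation of log2 fold changes across pairs of 0.290 on the same strand (95% interval 0.201 to 0.379, 1246 pairs) and 0.225 on opposite strands (0.0737 to 0.358, 1019 pairs), and 0.02 over 10000 nt. Loci are not independent replicates. If neighbours were pieces of one transcript, the same strand would correlate more. The difference of 0.0645 was below the bound of 0.1 written beforehand for the opposite case, but the intervals overlap by more than that bound, so pieces of one transcript may or may not account for it.

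Annotated genes with adjacent numbers in their IDs were called in the same direction in 234 pairs between green and yellow rRNA-depleted fruit, against a mean of 121 and a highest value of 155 in 1000 shuffles of gene order. In poly(A)-depleted fruit there were 330 pairs against a mean of 258.5 and a highest of 303. The longest run, from FvH4_3g17790 to FvH4_3g17840, held 6 genes called lower in rRNA-depleted yellow fruit. Reads that span neighbours, or neighbours of one gene family, were not tested.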
